A study of Mus musculus with 7 samples.

How the data were processed

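Dorsal skin of male HR-1 mice, a hairless strain, was compared between mice fed an AIN-93G diet that contained glucosylceramide (GC) and mice fed the same diet without it. Each of 7 Agilent whole mouse genome 4x44K arrays held a sample of GC-fed and a sample of control-fed skin RNA, the pair carrying Cy3 and Cy5 dye. On 3 arrays the skin was taken before treatment with the detergent sodium dodecyl sulfate (SDS), after 12 days of diet; on 4 arrays it was taken after 2 days of SDS, at 14 days of diet. The labels give 500 ng of total RNA per labelling, an age of 5 weeks and SDS at 10%. The GC-fed sample carried Cy3 on 1 of the before-SDS arrays and on 2 of the after-SDS arrays, and Cy5 on the others.

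Per the file headers, the scanner files hold spot intensity in each channel, extracted with Agilent Feature Extraction 9.1.3.1: the mean pixel brightness of a spot, the median brightness of its local background, and a processed intensity that the authors' software had corrected for background and normalized between the dyes. A gene-level table deposited by the authors holds intensity per gene, with values under 200 set to 200, and a log2 ratio of GC-fed over control-fed that the authors calculated from it. That the sign of this deposited log2 ratio was turned on the arrays with the GC-fed sample in Cy3 was read from its values. The deposited table served as an alternative only; it held 13088 genes, of which 10822 were used. Across genes, its ratio correlated with the ratio from the scanner values at r between 0.867 and 0.977 on the 7 arrays; genes are not independent replicates.

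The mean signal was corrected against the local background by limma's normexp method with an offset of 50, and each array's log2 ratios were normalized by loess with control spots at weight 0. Control spots and spots marked as non-uniform or as population outliers were left out, which took 4 to 27 spots per array. The 41174 probes were named by accession (22951), by the current symbol in the file (6659) or by an older symbol brought up to date (3109); the other 8455 kept the file's name. Probes well above background in at least 3 of the 14 channels were kept, 25175 in all. Of the probes of a gene, the 1 with the highest mean intensity was used, which left 17110 genes. Each array had 43379 spots that were not controls, and none was saturated. Between 48.5% and 54.5% of them were well above background in the green channel, and between 58.2% and 62.8% in the red channel. Precision was limited by the number of arrays.

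The diet effects before and after SDS and their difference came from 1 limma fit (lmFit and eBayes) to the log2 ratios of all 7 arrays, with a coefficient for the diet effect in each group and a dye term for each probe. The SDS effects in control-fed and in GC-fed mice came from limma's separate-channel analysis of the 14 channels in 4 groups, after Aquantile normalization between arrays, with the dye as a term and an estimated correlation within spots of -0.006. Residual degrees of freedom were 4 in the ratio fit and 9 in the channel fit, and eBayes added 2.7 and 3.37. No gene passed for the dye term (0 genes). P-values were adjusted by Benjamini and Hochberg over the 17110 genes, with 0.05 as the threshold; they measure the spread between samples, and the labels number the replicates without saying whether each came from a separate animal or from pooled RNA. Log2 fold changes are printed with the standard error (SE) of limma's fit, and group values as mean and SD.

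In all, 30 gene lists with 822 members were fixed, of which 789 had a probe. They were the cornified envelope, tight junction, suprabasal keratinocyte differentiation, ceramide and sphingolipid metabolism, epidermal lipid barrier, cholesterol synthesis, PPAR target, basal keratinocyte, wound and hyperproliferation keratinocyte, cell cycle, cytokine and chemokine, interferon response, NRF2 and oxidative stress, heat shock and immediate early, circadian clock, and collagen and extracellular matrix lists. The others were markers of skeletal muscle, adipocyte, sebaceous gland, hair follicle, melanocyte, endothelial, neutrophil, macrophage and monocyte, dendritic and Langerhans, T and NK, B and plasma, mast, erythrocyte, and nerve and Schwann cells. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists of a comparison. The test was repeated with an estimated correlation and with fry, which tests whether a list's genes move, on balance, one way. Genes of a list were also adjusted over the list alone.

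Named genes followed a rule. It took the 10 largest rises and falls among genes that passed, went the same way on every array (for SDS, groups that did not overlap) and had an ordinary symbol; where none passed, it took the 5 genes with the smallest p in each direction. From each list that passed, and from the cornified envelope and tight junction lists always, it took up to 4 members with the smallest p in the list's direction. It also took fixed genes, among them Flg, Lor, Ivl, Tgm1, Tgm3, Cldn1, Cldn12, Ocln, Ugcg, Krt10, Krt6b, Krt16, Il1b and Mki67. Some genes that this rule took are not reported here.

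Simulated data had the real ratios' spread but independent genes, 100 changed 2-fold and 100 4-fold, so real recovery may differ. The fits recovered 80% and 95% of these for the diet effect before SDS, 87% and 97% after SDS, 68% and 88% for the difference, 92% and 95% for SDS in control-fed and 84% and 95% in GC-fed mice, with 7 to 16 false calls. A cornified list shifted by 0.5 was called (adjusted p 4.42e-23) and 0 others, a test without correlated genes.

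Comparisons, tests, lists, the naming rule and most alternatives were fixed before the data were examined. These alternatives changed the background correction, the normalization within and between arrays, the filter on dim probes, the outlier marks, the choice of probe, the dye term, the variance model and the arrays in the fit, used the deposited table or replicate number as a block, and left out each array in turn. Alternatives that turned the sign of an array opposed to its group, or left out 2 arrays, were chosen after seeing the data. Agilent control spots were left out because they measure no gene. Software was R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.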

Results

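RNA of dorsal skin was measured on 7 arrays, each of which held a sample of GC-fed skin and a sample of control-fed skin. Before SDS, 3 arrays gave 3 samples per diet, and after 2 days of SDS, 4 arrays gave 4 samples per diet. GC is a sphingolipid in which a sugar is bound to ceramide, a main lipid of the skin's outer barrier, and SDS is a detergent that damages that barrier. Diet effects are log2 ratios of GC-fed over control-fed, and levels are log2 intensities. The median signal of a spot lay between 178.5 and 240.1 in the green channel and between 179.8 and 207.8 in the red channel, over a median local background of 53.5 to 59. The before-SDS arrays shared 1 slide and scan and the after-SDS arrays another, and 0 slides held both, so the effects of SDS and of slide cannot be told apart.

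The after-SDS arrays split by direction. Across genes, which are not independent replicates, the ratios of after-SDS array 4 correlated with those of arrays 1, 2 and 3 at r = -0.5, -0.62 and -0.3. Arrays 1, 2 and 3 correlated with each other at r between 0.32 and 0.5. Before SDS, array 1 correlated with arrays 2 and 3 at r = -0.4 and -0.18, and arrays 2 and 3 with each other at 0.23. That array 1 was the only 1 of them with the GC-fed sample in Cy3, and as red over green the same correlations were 0.4, 0.18 and 0.23, so this split ran along the dye. After SDS, as red over green, arrays 1, 2 and 4 correlated at 0.5 to 0.62 and array 3 with them at -0.3 to -0.43, although arrays 3 and 4 carried the same dyes. The labelled direction was kept for every value, and each list that passed after SDS is given also without array 4. Ratios beyond 0.25 in the same direction on all 4 after-SDS arrays occurred for 45 genes as labelled and for 817 genes with the sign of array 4 turned.

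**Figure D1:**
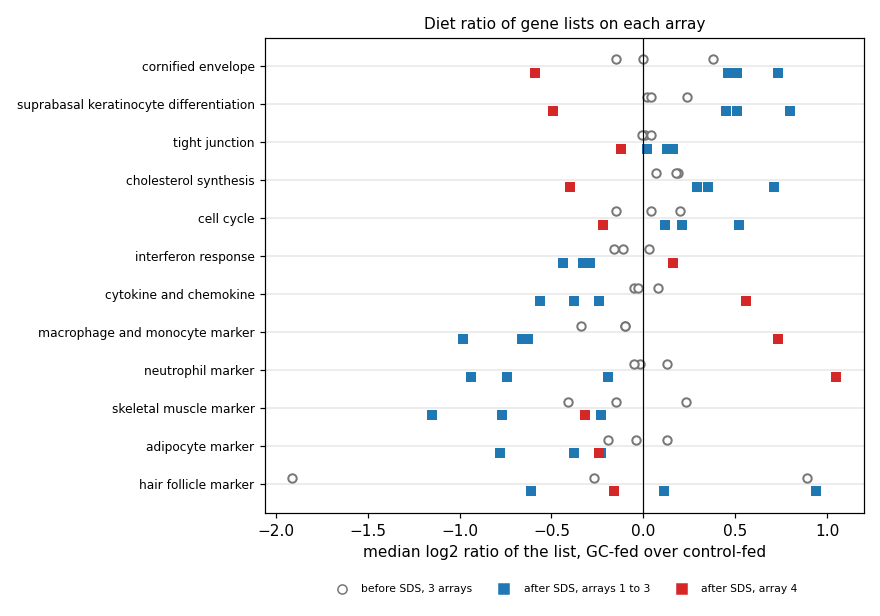
Median log2 ratio of GC-fed over control-fed skin (x axis) for 12 gene lists (y axis), with 1 point per array: open grey circles for the 3 arrays before SDS, blue squares for after-SDS arrays 1 to 3 and red squares for after-SDS array 4. The cornified envelope list lay between 0.46 and 0.73 on after-SDS arrays 1 to 3 and at -0.59 on array 4, while the skeletal muscle list lay below 0 on all 4.

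The first comparison asks which transcripts differed between the diets in skin without SDS. Genes of cholesterol synthesis had 25 of 25 above 0 with a median of 0.21 (adjusted p = 1.25e-10, and adjusted p = 0.871 with an estimated correlation). Acat2, which makes the first intermediate of the pathway, was at 0.26 (SE 0.10) and Cyp51, a sterol demethylase, at 0.39 (SE 0.22), both higher on 3 of 3 arrays. Interferon response genes had 30 of 36 below 0 with a median of -0.11 (adjusted p = 1.36e-08 and 0.871). Isg15, a ubiquitin-like protein induced by interferon, was at -0.38 (SE 0.12), Rtp4 at -0.57 (SE 0.25), Irf7 at -0.26 (SE 0.12) and Oas2 at -0.28 (SE 0.14), each lower on 3 of 3 arrays, although the list's medians were -0.16, 0.03 and -0.11, with 22 of 36 genes higher on array 2. None of these genes passed alone, and 0 genes of either list passed when adjusted over the list alone. Without before-SDS array 1 the cholesterol median was 0.41.

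Lists of the epidermal barrier had small positive medians before SDS. The epidermal lipid barrier list had 25 of 31 genes above 0 with a median of 0.15 (adjusted p = 0.000238, and adjusted p = 0.871 with an estimated correlation). Elovl4, which makes the very long fatty acids of skin ceramides, was at 0.39 (SE 0.28) and Slc27a4, a fatty acid transporter, at 0.31 (SE 0.18), both higher on 3 of 3 arrays. Suprabasal keratinocyte differentiation had 25 of 27 genes above 0 with a median of 0.13 (adjusted p = 0.000261 and 0.871). Ceramide and sphingolipid metabolism had 23 of 35 above 0 with a median of 0.05 (adjusted p = 0.00819 and 0.871). Kdsr, an enzyme of ceramide synthesis, was at 0.33 (SE 0.15). Basal keratinocyte genes were above 0 in 14 of 18 with a median of 0.12 (adjusted p = 0.0165 and 0.871). The cornified envelope list, the cross-linked protein shell of dead keratinocytes, had 36 of 44 above 0 with a median of 0.10 (adjusted p = 0.0165 and 0.887). On arrays 1, 2 and 3 its median was -0.15, 0.38 and 0. The tight junction list had a median of 0.03 and did not pass (adjusted p = 0.135). None of the genes in these 6 lists passed, and 0 passed when adjusted over the list alone.

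These epidermal calls depended on single arrays. Without before-SDS array 2 the cornified median turned to -0.06, and the suprabasal (0.04), epidermal lipid (0.07) and ceramide (0.01) lists no longer passed. Without before-SDS array 1 the medians were 0.57 for cornified, 0.42 for suprabasal, 0.32 for epidermal lipid, 0.18 for ceramide and 0.24 for basal genes, and the tight junction list passed at 0.07. The basal list was at 0.07 without before-SDS array 2 and lost its call without before-SDS array 3 (0.03) or after-SDS array 4 (0.09), which was part of the same fit. The cornified list lost its call without before-SDS array 3 (0.09), after-SDS array 1 (0.05) or after-SDS array 4 (0.04), and the tight junction list passed at 0.04 without after-SDS array 3.

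Other cell types and processes also had small diet ratios before SDS. Sebaceous gland markers were above 0 in 14 of 16 with a median of 0.13 (adjusted p = 1.23e-05, and adjusted p = 0.871 with an estimated correlation), with Fasn, the fatty acid synthase, at 0.24 (SE 0.11) but lower on array 3. Macrophage and monocyte markers were below 0 in 22 of 25 with a median of -0.27 (adjusted p = 1.43e-05, and adjusted p = 0.871 with an estimated correlation), and Fcgr1, an antibody receptor, was at -0.39 (SE 0.15) and lower on 3 of 3 arrays. Hair follicle markers were below 0 in 30 of 31 with a median of -0.40 (adjusted p = 1.23e-05, and adjusted p = 0.871 with an estimated correlation), though the arrays gave 0.89, -1.91 and -0.27. Cell cycle genes had a median of 0.08 (adjusted p = 0.011 and 0.904). Collagen and extracellular matrix genes had a median of 0.06 (adjusted p = 0.021 and 0.887). Heat shock and immediate early genes had a median of 0.03 (adjusted p = 0.0302 and 0.871). Nr4a1, an early-response nuclear receptor, was at 0.64 (SE 0.22) and higher on 3 of 3 arrays. Skeletal muscle markers had 22 of 30 genes below 0 and a median of -0.14 (adjusted p = 0.0396, and adjusted p = 0.887 with an estimated correlation). In these 7 lists 0 genes passed, over all genes or adjusted over the list alone.

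Without before-SDS array 1 the medians turned to -0.06 for cell cycle, -0.06 for collagen, -0.06 for heat shock and 0.17 for muscle, which passed that way (adjusted p 0.0106), and were 0.22 for sebaceous, -0.52 for macrophage and -1.50 for hair follicle markers. In each fit without before-SDS array 1 the dye term came from the after-SDS arrays alone. Without before-SDS array 2 the hair follicle median turned to 0.23 and passed that way (adjusted p 9.67e-05), the sebaceous (0.05) and muscle (-0.14) lists no longer passed, and collagen was at 0.15 and heat shock at 0.05. Without before-SDS array 3 the macrophage (-0.07), cell cycle (0.05) and collagen (0.00) lists no longer passed, with muscle at -0.33 and heat shock at 0.10. Leaving out an after-SDS array from the shared fit also mattered: without array 1 muscle lost its call (-0.12), without array 3 collagen (0.03) and heat shock (0.00) did, and without array 4 muscle did (-0.12), with cell cycle at 0.04, macrophage at -0.15 and heat shock at 0.05.

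Among single genes before SDS, the smallest p-values belonged to Edn1, the vasoconstrictor endothelin-1, at -0.33 (SE 0.08, ratios -0.32, -0.30 and -0.25) and to Aldh1a3, an enzyme of retinoic acid synthesis, at -0.54 (SE 0.14, ratios -0.35, -0.59 and -0.74). Rbm47 was at 0.32 (SE 0.09) and Cdkn2c, a cell cycle inhibitor, at 0.24 (SE 0.08), both higher on 3 of 3 arrays. Gpr155 was at 0.23 (SE 0.07), Oat at 0.20 (SE 0.06), H4c9 at -0.41 (SE 0.12) and Mest at -0.64 (SE 0.19). Ogfrl1 was at -0.62 (SE 0.18), but its other probe gave 0.12. Filaggrin (Flg) was at 0.40 (SE 0.46), loricrin (Lor) at 0.25 (SE 0.51), involucrin (Ivl) at -0.02 (SE 0.25) and Tgm1, which cross-links the envelope, at 0.03 (SE 0.22). Ugcg, the enzyme that makes GC in cells, was at 0.04 (SE 0.09). In limma, 0 genes passed in this comparison (lowest adjusted p 1), with 68 at an unadjusted p under 0.05 (40 higher, 28 lower) where 856 would be expected by chance. The camera test called 14 lists at the preset correlation, from 9 (without before-SDS array 2) to 17 without 1 array, and 9 without the dye term. It called 0 lists with an estimated correlation, and fry called 0 (lowest adjusted p 0.997). The median SE was 0.10.

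The second comparison asks which transcripts differed between the diets after SDS. The cornified list was higher and the macrophage list lower on arrays 1 to 3, and the reverse on array 4. The cornified envelope median was 0.73, 0.51 and 0.46 on arrays 1 to 3, with 41, 39 and 36 of 44 genes higher, and -0.59 on array 4, with 5 of 44 higher. The macrophage and monocyte median was -0.66, -0.63 and -0.98 on arrays 1 to 3 and 0.73 on array 4. Fat and muscle markers were lower on all 4. With all 4 arrays limma called 0 genes (lowest adjusted p 0.835), with 763 at an unadjusted p under 0.05 (286 higher, 477 lower). Without array 4, singled out for opposing the rest, it called 926 (250 up, 676 down), which that choice favours.

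Barrier genes after SDS had positive medians over all 4 arrays. The cornified envelope list had 37 of 44 above 0 with a median of 0.35 (adjusted p = 3.35e-06, and adjusted p = 0.63 with an estimated correlation). Its median was 0.60 without array 4, 0.23 without array 3, and 0.10 with the call lost without array 1. Evpl, which encodes the envelope protein envoplakin, was at 0.35 (SE 0.17) and without array 4 passed at 0.60 (SE 0.10, adjusted p 0.0253), with -0.40 on array 4. Krtdap, a keratinocyte differentiation protein, was at 0.47 (SE 0.24), or 0.80 without array 4 (adjusted p 0.0485), with -0.35 on array 4. Tgm1 was at 0.32 (SE 0.19), or 0.61 without array 4 (adjusted p 0.0152), with -0.54 on array 4. Flg was at 0.48 (SE 0.39), Lor at 0.55 (SE 0.43) and Ivl at 0.21 (SE 0.21), and did not pass without array 4 either, at 1.00, 1.14 and 0.52. On array 4 these 3 were at -1.11, -1.15 and -0.76. Tgm3 was at 0.04 (SE 0.14).

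Suprabasal keratinocyte differentiation had 26 of 27 genes above 0 with a median of 0.31 (adjusted p = 2.2e-08, and adjusted p = 0.63 with an estimated correlation), and its median was 0.62 without array 4, 0.17 without array 3 and -0.49 on array 4. Klk7, a protease of skin shedding, was at 0.39 (SE 0.14), or 0.57 without array 4 (adjusted p 0.0337), with -0.20 on array 4. Spink5, an inhibitor of such proteases, was at 0.64 (SE 0.27), or 1.00 without array 4 (adjusted p 0.0471), with -0.49 on array 4. Krt10, the main keratin of suprabasal cells, was at 0.58 (SE 0.37). Tight junction genes had a median of 0.09 (adjusted p = 0.198), 0.19 without array 4, where the list passed (adjusted p = 0.00829), and -0.12 on array 4. Claudin 1 (Cldn1), which seals epidermal junctions, was at 0.25 (SE 0.15), Ocln at 0.24 (SE 0.12), F11r at 0.22 (SE 0.10) and Cldn12 at 0.01 (SE 0.07). None of them passed without array 4.

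Lipid genes after SDS had positive medians too. The epidermal lipid barrier list had 24 of 31 above 0 with a median of 0.13 (adjusted p = 0.00195, and adjusted p = 0.64 with an estimated correlation). Its median was 0.23 without array 4 and -0.37 on array 4, and the call was lost without array 1 (0.07) or array 3 (0.07). Fa2h, which makes the hydroxylated fatty acids of skin ceramides, was at 0.61 (SE 0.20) with -0.10 on array 4, and Elovl4 at 0.51 (SE 0.24) with -0.49 on array 4. Cholesterol synthesis had 24 of 25 above 0 with a median of 0.25 (adjusted p = 2.37e-08, and adjusted p = 0.63 with an estimated correlation), at 0.48 without array 4, 0.12 without array 1 or array 3, and -0.40 on array 4. Lss, the lanosterol synthase, was at 0.34 (SE 0.12, other probes 0.04 and 0.17), or 0.50 without array 4 (adjusted p 0.0307), with -0.01 on array 4. Ceramide and sphingolipid metabolism had a median of 0.06 and did not pass (adjusted p = 0.0895), with Ugcg at 0.07 (SE 0.08). In the barrier and lipid lists 0 genes passed with all arrays, over all genes or adjusted over the list alone. Without array 4, 7 cornified, 7 suprabasal, 6 epidermal lipid and 5 cholesterol genes rose.

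Basal keratinocyte and cell cycle lists had positive medians after SDS, with 0 genes passing, over all genes or adjusted over the list alone, and 3 basal and 1 cell cycle gene without array 4. The basal list had 16 of 18 genes above 0 with a median of 0.18 (adjusted p = 2.31e-05, and adjusted p = 0.63 with an estimated correlation), at 0.27 without array 4, 0.08 without array 3 and -0.14 on array 4. Col17a1, a collagen that anchors basal cells, was at 0.32 (SE 0.16), or 0.57 without array 4 (adjusted p 0.0219), with -0.25 on array 4. The cell cycle list had 40 of 40 genes above 0 with a median of 0.17 (adjusted p = 4.2e-09, and adjusted p = 0.63 with an estimated correlation), at 0.29 without array 4 and -0.22 on array 4, and without array 3 the call was lost at 0.00. Mki67, a proliferation marker, was at 0.46 (SE 0.18), or 0.72 without array 4 (adjusted p 0.0242), with -0.39 on array 4. Keratins of wounded skin were near 0, with Krt6b at 0.01 (SE 0.13) and Krt16 at -0.05 (SE 0.28).

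Immune genes after SDS had negative medians. The interferon response list had 36 of 36 genes below 0 with a median of -0.21 (adjusted p = 3.35e-12, and adjusted p = 0.63 with an estimated correlation), at -0.34 without array 4, -0.10 without array 3 and 0.16 on array 4. Psmb9, a subunit of the immunoproteasome, was lower on 4 of 4 arrays at -0.27 (SE 0.07), and Isg15 was at -0.32 (SE 0.10) with 0.07 on array 4. The cytokine and chemokine list had 31 of 35 below 0 with a median of -0.17 (adjusted p = 0.000348, and adjusted p = 0.63 with an estimated correlation). Its median was -0.35 without array 4 and 0.56 on array 4, and the call was lost without array 2 (-0.08) or array 3 (-0.07). Il1b, an inflammatory cytokine, was at -1.0 (SE 0.52), with -0.96, -2.0 and -2.14 on arrays 1 to 3 and 1.08 on array 4, and without array 4 fell by 1.84 (adjusted p 0.00719). Ccl4, a chemokine, was at -1.27 (SE 0.55), with 0.68 on array 4, and without array 4 fell by 2.09 (adjusted p 0.0205). Ccl11 was at -0.63 (SE 0.30) with 0.47 on array 4, and without array 4 it fell by 1.10 and Isg15 fell by 0.44.

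Macrophage and monocyte markers had 24 of 25 genes below 0 after SDS with a median of -0.44 (adjusted p = 1.42e-07, and adjusted p = 0.63 with an estimated correlation), at -0.88 without array 4 and -0.15 without array 3. C1qb, a complement subunit made by macrophages, was at -0.57 (SE 0.25) with 0.19 on array 4, and Ms4a7 at -0.55 (SE 0.27) with 0.73 on array 4. Mast cell markers had 14 of 14 below 0 with a median of -0.23 (adjusted p = 2.2e-08, and adjusted p = 0.63 with an estimated correlation), at -0.35 without array 4, -0.10 without array 3 and -0.08 on array 4. Cma1, a mast cell chymase, was lower on 4 of 4 arrays at -0.74 (SE 0.18), and so was Mcpt4 at -0.54 (SE 0.15). Without array 4, C1qb (-0.96), Ms4a7 (-0.99), Cma1 (-0.98) and Mcpt4 (-0.70) fell. Endothelial markers had 16 of 17 below 0 with a median of -0.16 (adjusted p = 2.54e-05, and adjusted p = 0.63 with an estimated correlation), at -0.23 without array 4 and -0.01 on array 4, and without array 3 the call was lost at -0.03. In the immune and endothelial lists 0 genes passed with all arrays, over all genes or adjusted over the list alone. Without array 4, 19 macrophage, 14 cytokine, 10 interferon and 7 neutrophil genes fell.

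Fat and muscle markers were lower in GC-fed skin on all 4 after-SDS arrays. Adipocyte markers had 19 of 20 genes below 0 with a median of -0.40 (adjusted p = 4.5e-15, and adjusted p = 0.63 with an estimated correlation), at -0.59 without array 4, -0.22 without array 3 and -0.24 on array 4. Gpd1, which supplies glycerol for fat, was at -0.49 (SE 0.07, ratios -0.26, -0.38, -0.80 and -0.51, other probe -0.22) and without array 4 fell by 0.55 (adjusted p 0.014). Plin1, which coats fat droplets, was at -0.56 (SE 0.10), Thrsp at -0.77 (SE 0.15) and Slc2a4, the insulin-responsive glucose transporter, at -0.61 (SE 0.13), each lower on 4 of 4. No adipocyte gene passed over all genes (0 of 20), 10 fell when adjusted over the list alone, and 5 fell without array 4, among them Plin1 (-0.67) and Thrsp (-0.90). Skeletal muscle markers had 27 of 30 genes below 0 with a median of -0.70 (adjusted p = 4.5e-15, and adjusted p = 0.63 with an estimated correlation), at -0.74 without array 4, -0.41 without array 3 and -0.32 on array 4. Pvalb, a calcium-binding protein of fast fibres, was at -1.34 (SE 0.32) but -0.05 on array 4. Myoz1 was at -1.04 (SE 0.25) and Ckm, muscle creatine kinase, at -1.07 (SE 0.28), both lower on 4 of 4. No muscle gene passed over all genes (0 of 30), 17 fell when adjusted over the list alone, and 8 fell without array 4, among them Pvalb (-1.71), Myoz1 (-1.26) and Ckm (-1.33).

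The genes with the smallest p-values after SDS were ranked with array 4 as labelled, which favours genes with the same sign on it. Wwc1 was at 0.88 (SE 0.12), with 0.39, 0.72, 1.39 and 1.01 on the 4 arrays. Mug1, a protease inhibitor, was at 1.61 (SE 0.25, ratios 1.16 to 2.02) and Serpina3b, a serpin, at 1.03 (SE 0.17, ratios 0.86 to 1.19), both higher on 4 of 4. Slc38a2, an amino acid transporter, was at 0.29 (SE 0.06) and Cst6, a protease inhibitor of the skin, at 0.36 (SE 0.08) but -0.26 on array 2. Ifi27l2a, an interferon-induced gene, was at -3.51 (SE 0.50), with -2.03, -0.85, -5.08 and -6.10 on the 4 arrays and -0.84, -1.07 and -1.61 before SDS. Aldh1l1, a folate enzyme, was at -0.39 (SE 0.07) and Serpinh1, a collagen chaperone, at -0.46 (SE 0.08), both lower on 4 of 4. None of these genes passed with all arrays (adjusted p = 0.835). Without array 4, Wwc1 (0.90), Mug1 (1.74) and Serpina3b (1.07) rose, and Ifi27l2a (-3.0), Aldh1l1 (-0.45), Serpinh1 (-0.48) and Plin1 (-0.67) fell.

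Lists that did not pass after SDS with all arrays were NRF2 and oxidative stress (median -0.09, adjusted p = 0.149), PPAR target (-0.05, 0.149), T and NK cell (-0.05, 0.149), B and plasma cell (-0.05, 0.198), dendritic and Langerhans cell (-0.08, 0.0895) and neutrophil (-0.20, 0.0956). The others were heat shock (-0.05, 0.265), circadian clock (-0.06, 0.384), erythrocyte (-0.41, 0.161), hair follicle (0.07, 0.397), melanocyte (0.04, 0.776), sebaceous gland (0.03, 0.844) and nerve and Schwann cell (-0.02, 0.63). The wound and hyperproliferation list had a median of 0.04 and a mean of -0.06 (adjusted p = 0.779), and the collagen list a median of -0.05 with an upward test (adjusted p = 0.828). In all, camera called 13 lists, 22 without array 4 and 12 to 22 over all single arrays left out, and 0 with an estimated correlation. The 9 gained without array 4 were tight junction (0.19), ceramide (0.15), melanocyte (0.38), NRF2 (-0.17), heat shock (-0.14), collagen (-0.23), neutrophil (-0.64), dendritic (-0.18) and erythrocyte (-0.76). By fry 0 lists passed (lowest adjusted p 0.426). With the sign of array 4 turned, a choice made after seeing the data, limma called 1837 genes (682 rose, 1155 fell).

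**Figure D2:**
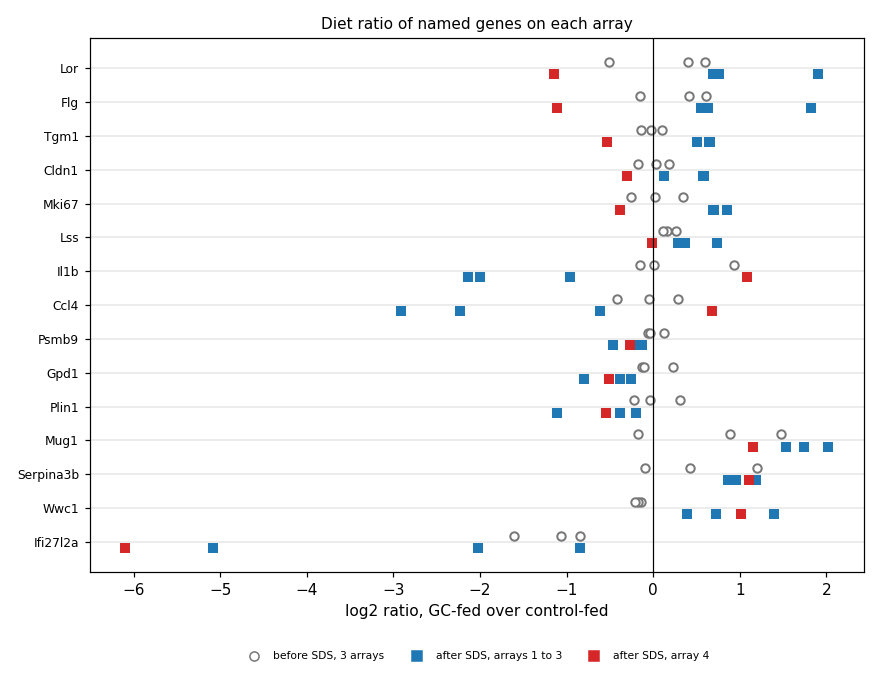
Log2 ratio of GC-fed over control-fed skin (x axis) for 15 named genes (y axis), with 1 point per array: open grey circles for the 3 arrays before SDS, blue squares for after-SDS arrays 1 to 3 and red squares for after-SDS array 4. Lor was at -1.15 on array 4 and between 0.69 and 1.90 on arrays 1 to 3, whereas Gpd1, Plin1, Mug1, Serpina3b, Wwc1 and Ifi27l2a kept 1 direction on all 4.

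The third comparison asks whether the diet effect differed between skin after and before SDS. Adipocyte markers had a median difference of -0.28 (adjusted p = 2.03e-12, and 0.916 with an estimated correlation). Muscle markers were at -0.49 (adjusted p = 1.78e-09 and 0.916). Mast cell markers were at -0.25 (adjusted p = 1.13e-07 and 0.916) and endothelial markers at -0.14 (adjusted p = 0.00324 and 0.916). Gpd1 differed by -0.54 (SE 0.11), Plin1 by -0.66 (SE 0.16), Tnnt1, a troponin of slow muscle, by -0.67 (SE 0.26) and Cma1 by -0.76 (SE 0.28). None of these passed over all genes, and 4 adipocyte genes fell when adjusted over the list alone. Without array 4 the medians were -0.44 for adipocyte and -0.24 for endothelial markers, and without after-SDS array 3 they were -0.16 for adipocyte, -0.23 for muscle, -0.13 for mast cell and 0.01 for endothelial markers, the last without a call. Endothelial markers lost the call also without before-SDS array 1 (-0.16), where mast cell markers were at -0.42, and muscle was at -0.32 without before-SDS array 3.

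Epidermal lists differed in the other direction. Cornified envelope genes had a median difference of 0.25 (adjusted p = 0.0359, and 0.941 with an estimated correlation). Suprabasal genes were at 0.22 (adjusted p = 0.0242 and 0.916) and cell cycle genes at 0.11 (adjusted p = 0.00213 and 0.916). Hair follicle markers had 31 of 31 genes above 0 with a median of 0.39 (adjusted p = 0.00103 and 0.916). The tight junction median was 0.03 (adjusted p = 0.942). Evpl differed by 0.39 (SE 0.26), Krt80 by 0.27 (SE 0.13) and Mki67 by 0.35 (SE 0.28). Without array 4 the medians were 0.62 for cornified, 0.50 for suprabasal and 0.25 for cell cycle genes, and the tight junction list passed at 0.12. Without before-SDS array 1 they turned to -0.37 for cornified, which passed that way (adjusted p 0.00782), and -0.14 for suprabasal genes, with cell cycle at 0.23 and hair follicle at 1.42. The cornified call was lost without after-SDS array 1 (0.04), 2 (0.21) or 3 (0.10), and the suprabasal call without array 1 (0.11), where hair follicle was at 0.70. Without after-SDS array 3 the suprabasal median was 0.02 with a downward test, cell cycle turned and passed that way (-0.07, adjusted p 4.13e-05), and hair follicle turned (-0.08). Without before-SDS array 2, cell cycle lost its call (0.06) and hair follicle turned to -0.21.

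Immune and remaining lists had small differences. Interferon response was at -0.11 (adjusted p = 0.0284, and 0.916 with an estimated correlation). Cytokine and chemokine genes were at -0.13 (adjusted p = 0.0475 and 0.916). T and NK cell markers were at -0.07 (adjusted p = 0.0416 and 0.916). Heat shock and immediate early genes were at -0.03 (adjusted p = 0.0359 and 0.916) and sebaceous markers at -0.02 (adjusted p = 0.0359 and 0.916). Il1b differed by -1.24 (SE 0.81), Nr4a1 by -1.01 (SE 0.29) and Fasn by -0.50 (SE 0.14). Without array 4 the medians were -0.23 for interferon, -0.38 for cytokine, -0.15 for T and NK cell and -0.20 for heat shock genes, and the sebaceous call was lost (-0.02). Each call was also lost or turned without another array. Interferon was at 0.06 without after-SDS array 3, -0.11 without after-SDS array 1 and -0.07 without before-SDS array 1 or 2. Cytokine genes were at 0.02 without after-SDS array 3, -0.18 without array 1, -0.08 without array 2 and 0.00 without before-SDS array 1. T and NK cell markers were at -0.06 without after-SDS array 2, 0.00 without array 3, -0.13 without before-SDS array 1 and 0.00 without before-SDS array 2. Heat shock genes were at 0.00 without after-SDS array 2, -0.06 without array 3 and 0.04 without before-SDS array 1, and sebaceous markers at 0.00 without after-SDS array 2 and 0.01 without before-SDS array 2. The wound list had a median of 0.04 with a downward test.

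Among single genes, Wwc1 differed by 1.11 (SE 0.19), Unc45a by 0.80 (SE 0.19), Zfp68 by 0.51 (SE 0.14) and Edn1 by 0.38 (SE 0.11). Pcx, which makes oxaloacetate from pyruvate, differed by -0.53 (SE 0.10), Cdkn2c by -0.51 (SE 0.10), Aldh1l1 by -0.53 (SE 0.11) and Cdo1, an enzyme of cysteine breakdown, by -0.82 (SE 0.17). Slit3 differed by 0.92 (SE 0.21), but its other probe gave -0.26. In limma, 0 genes passed for this difference (lowest adjusted p 1), with 207 at an unadjusted p under 0.05 (105 higher, 102 lower), also under the 856 expected by chance. Without after-SDS array 4 it called 56 genes (2 rose, 54 fell), among them Il1b (-2.24). The camera test called 13 lists, 24 without array 4 and 8 without after-SDS array 2 or 3, and 0 with an estimated correlation. By fry 0 lists passed (lowest adjusted p 0.974). The median SE was 0.13, and this comparison carries the slide limit as well.

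The fourth comparison asks what 2 days of SDS changed in control-fed skin, together with the change of slide and of days of diet. Hair follicle markers had 31 of 31 above 0 with a median of 1.05 (adjusted p = 3.35e-09, and 0.628 with an estimated correlation). Over all genes 13 rose, and 19 when adjusted over the list alone. The hair keratin Krt35 rose by 1.97 (SE 0.40), from 12.58 ± 0.97 (SD, n = 3) to 14.52 ± 0.40 (SD, n = 4), Krt85 by 1.47 (SE 0.27) and Krt33b by 1.64 (SE 0.38). Cell cycle genes had 34 of 40 above 0 with a median of 0.27 (adjusted p = 9.96e-07, and 0.628 with an estimated correlation). Over all genes 14 rose, and 17 when adjusted over the list alone. Aurka, a mitotic kinase, rose by 0.88 (SE 0.13) and Cenpe, a mitotic motor, by 0.91 (SE 0.19, other probes 0.10 and 0.18). Melanocyte markers had a median of 0.44 (adjusted p = 0.00466, and 0.499 with an estimated correlation). Of 11, 4 rose over all genes and 7 adjusted over the list alone, with Dct, a melanin enzyme, at 1.58 (SE 0.35). Wound and hyperproliferation genes had a median of 0.25 (adjusted p = 0.0182, and adjusted p = 0.628 with an estimated correlation), with 5 of 33 higher over all genes and 5 adjusted over the list alone. Krt16, a keratin of wounded epidermis, rose by 1.11 (SE 0.31), and Krt6b was at 0.68 (SE 0.28) and did not pass. The hair follicle median was 0.42 without before-SDS array 1 and 1.62 without before-SDS array 2, and the wound call was lost without before-SDS array 1 (0.18).

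Barrier lists had negative medians in control-fed skin. Ceramide and sphingolipid metabolism had 27 of 35 genes below 0 with a median of -0.23 (adjusted p = 0.00368, and adjusted p = 0.499 with an estimated correlation); 10 fell and 1 rose over all genes, and 13 and 2 when adjusted over the list alone. Cers5, a ceramide synthase, fell by 0.91 (SE 0.13), from 12.98 ± 0.09 (SD, n = 3) to 12.03 ± 0.23 (SD, n = 4), and Sphk2, a sphingosine kinase, fell by 0.43 (SE 0.08). The epidermal lipid barrier list had a median of -0.28 (adjusted p = 0.00318, and adjusted p = 0.628 with an estimated correlation), with 8 of 31 lower over all genes and 10 adjusted over the list alone. Alox12b, a lipoxygenase of the lipid barrier, fell by 0.86 (SE 0.14) and Elovl1 fell by 0.78 (SE 0.12). The suprabasal median was -0.37 (adjusted p = 0.00122, and adjusted p = 0.628 with an estimated correlation), with 6 of 27 lower over all genes and 8 adjusted over the list alone. Krt80 fell by 0.79 (SE 0.10) and Krt2, a keratin of the upper epidermis, fell by 1.98 (SE 0.49). The cornified envelope median was -0.26 (adjusted p = 0.0108, and adjusted p = 0.7 with an estimated correlation), with 3 of 44 lower over all genes and 2 adjusted over the list alone. Ppl, the envelope protein periplakin, fell by 1.02 (SE 0.18), and Flg (-0.11, SE 0.32), Lor (-0.12, SE 0.35) and Ivl (-0.64, SE 0.22) did not pass.

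The tight junction median was -0.16 (adjusted p = 0.035, and 0.628 with an estimated correlation), with 4 of 35 lower over all genes and 4 adjusted over the list alone. Cldn1 fell by 0.65 (SE 0.14, other probe -0.20), from 10.44 ± 0.08 (SD, n = 3) to 9.77 ± 0.22 (SD, n = 4). Cldn23 fell by 0.68 (SE 0.17), while Ocln (-0.27, SE 0.13) and Cldn12 (-0.07, SE 0.08) did not pass. Basal keratinocyte genes had a median of -0.24 (adjusted p = 0.00266, and adjusted p = 0.499 with an estimated correlation), with 5 of 18 lower over all genes, and 8 lower and 1 higher adjusted over the list alone. Lamb3, a laminin chain of the basement membrane, fell by 0.63 (SE 0.12) and Col17a1 fell by 0.80 (SE 0.17). Cholesterol synthesis had a median of -0.20 (adjusted p = 0.0108, and 0.7 with an estimated correlation), with 3 of 25 lower over all genes and 1 adjusted over the list alone, among them Lss, which fell by 0.57 (SE 0.11). The circadian clock list had a median of -0.19 (adjusted p = 0.035, and 0.499 with an estimated correlation), with 4 of 18 lower over all genes and 4 adjusted over the list alone. Tef, a clock-driven factor, fell by 0.59 (SE 0.10, other probes -0.20 to -0.04). Without before-SDS array 1 the medians were 0.00 for cornified, -0.10 for suprabasal, -0.18 for epidermal lipid, -0.13 for tight junction, -0.14 for cholesterol and -0.09 for clock genes, all without a call, and -0.13 for ceramide genes. Other arrays ended calls as well: before-SDS array 2 for tight junction (-0.13), after-SDS array 1 for clock genes (-0.15), and after-SDS array 3 for cornified (-0.21), cholesterol (-0.16) and tight junction genes (-0.13), with suprabasal at -0.23. Without after-SDS array 4 the medians were -0.46 for cornified, -0.58 for suprabasal and -0.33 for cholesterol genes.

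Some immune lists and the fat list had positive medians in control-fed skin after SDS. Cytokine and chemokine genes had a median of 0.34 (adjusted p = 0.00349, and adjusted p = 0.628 with an estimated correlation), with 6 of 35 higher and 2 lower over all genes, and 9 and 2 adjusted over the list alone. Il1b rose by 1.73 (SE 0.49), from 8.92 ± 0.55 (SD, n = 3) to 10.67 ± 0.58 (SD, n = 4), Ccl4 by 1.72 (SE 0.48) and Cxcl13 by 1.20 (SE 0.27). Neutrophil markers had a median of 0.54 (adjusted p = 0.035, and adjusted p = 0.7 with an estimated correlation); 1 rose and 2 fell over all genes, and 2 rose and 2 fell when adjusted over the list alone. Clec4e, a receptor of myeloid cells, rose by 2.20 (SE 0.64). Adipocyte markers had a median of 0.37 (adjusted p = 0.00122, and adjusted p = 0.499 with an estimated correlation), with 6 of 20 higher over all genes and 9 adjusted over the list alone. Gpd1 rose by 0.50 (SE 0.07) and Adipoq, the hormone adiponectin, by 0.61 (SE 0.14). Mast cell markers had a median of 0.18 (adjusted p = 0.035 and 0.628), B and plasma cell markers 0.29 (adjusted p = 0.0108 and 0.499) and erythrocyte markers 0.69 (adjusted p = 0.0108 and 0.499). Over all genes 2 mast cell, 1 B and plasma cell and 1 erythrocyte gene rose, and 2, 1 and 3 adjusted over the list alone. Kit, a receptor of mast cells and melanocytes, rose by 0.44 (SE 0.07). Calls were lost for cytokine genes without before-SDS array 1 (0.27), for erythrocyte markers without before-SDS array 1 (0.51) and for neutrophil markers without before-SDS array 1 (0.42) or 3 (0.56) or after-SDS array 1 (0.52) or 3 (0.51). Mast cell markers lost theirs without before-SDS array 2 (0.11) or 3 (0.14) or after-SDS array 3 (0.10), and were at 0.29 without before-SDS array 1, and erythrocyte markers were at 0.34 without after-SDS array 3.

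The largest rise in control-fed skin was that of Slc4a7, a bicarbonate transporter, at 4.11 (SE 1.15), with levels of 9.41 ± 0.98 (SD, n = 3) and 13.48 ± 1.97 (SD, n = 4). Chil3, a macrophage lectin, rose by 2.55 (SE 0.64), Acod1, which makes itaconate in activated macrophages, by 2.09 (SE 0.65), Actn3, a protein of fast muscle fibres, by 2.03 (SE 0.49) and Sct by 1.68 (SE 0.42). Among the falls, Scd3, a fatty acid desaturase, fell by 2.05 (SE 0.18), Cthrc1 fell by 1.77 (SE 0.29), Serpina3b fell by 1.56 (SE 0.26), C7, a complement component, fell by 1.51 (SE 0.26), Neu2 fell by 1.3 (SE 0.26) and Clca3a1 fell by 1.26 (SE 0.17). Dst, H1f10 and Fbxo2 fell by 1.54 (SE 0.21), 1.54 (SE 0.34) and 1.35 (SE 0.16), but had other probes with values of 0.07, 0.03 and 0.12. In all limma called 2588 genes, 1138 up and 1450 down, with 5581 at an unadjusted p under 0.05 and a lowest adjusted p of 6.63e-06. Median centring in place of loess moved this split to 390 up and 777 down of 1167. With no normalization between arrays the median of all genes shifted by -0.26 and 0 genes passed, so changes are relative to the median gene.

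The count of genes in control-fed skin was 154 without before-SDS array 1, 1506 without before-SDS array 2, 1122 without before-SDS array 3, 1545 without after-SDS array 1 and 3688 at most. Of the 70 named genes that passed, 60 lost the call without before-SDS array 1, and 10 passed without each array in turn: Scd3, Cthrc1, Dst, Fbxo2, Clca3a1, Krt80, Cers5, Tef, Gpd1 and Kit. The camera test called 18 lists, from 10 (without before-SDS array 1) to 20 without 1 array, and 0 with an estimated correlation. By fry 7 lists passed (lowest adjusted p 0.0197).

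The fifth comparison asks what 2 days of SDS changed in GC-fed skin, again together with the change of slide and of days of diet. Hair follicle markers had 31 of 31 above 0 with a median of 1.59 (adjusted p = 6.74e-17, and 0.485 with an estimated correlation). Over all genes 26 rose, and 30 when adjusted over the list alone. Krt35 rose by 2.15 (SE 0.40), from 12.10 ± 0.63 (SD, n = 3) to 14.29 ± 0.30 (SD, n = 4), Krt85 by 1.63 (SE 0.27) and Hoxc13, a hair transcription factor, by 0.70 (SE 0.14). Cell cycle genes had 36 of 40 above 0 with a median of 0.42 (adjusted p = 2.11e-12, and 0.485 with an estimated correlation). Over all genes 24 rose, and 28 when adjusted over the list alone. Aurka rose by 0.91 (SE 0.13), Plk1, a mitotic kinase, by 0.84 (SE 0.14) and Mki67 by 0.71 (SE 0.20). Melanocyte markers had a median of 0.56 (adjusted p = 0.00277, and 0.485 with an estimated correlation). Of 11, 5 rose over all genes and 8 adjusted over the list alone. Wound and hyperproliferation genes had a median of 0.26 (adjusted p = 0.0204, and adjusted p = 0.601 with an estimated correlation), with 1 of 33 higher over all genes and 0 adjusted over the list alone. Gjb2, a connexin, rose by 0.94 (SE 0.28), and Krt16 was at 0.73 (SE 0.31) and Il1b at 0.49 (SE 0.49) without passing. The melanocyte median was 0.33 without after-SDS array 3, and the wound call was lost without before-SDS array 3 (0.20), after-SDS array 1 (0.18) or after-SDS array 4 (0.15).

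Barrier lists in GC-fed skin had negative medians too. Ceramide and sphingolipid metabolism had 28 of 35 below 0 with a median of -0.17 (adjusted p = 0.00375, and adjusted p = 0.485 with an estimated correlation); 5 fell and 2 rose over all genes, and 12 and 2 when adjusted over the list alone. Cers5 fell by 0.75 (SE 0.13), from 13.09 ± 0.08 (SD, n = 3) to 12.38 ± 0.30 (SD, n = 4), and Sgpp2 fell by 0.67 (SE 0.12). The epidermal lipid median was -0.31 (adjusted p = 0.00277, and adjusted p = 0.551 with an estimated correlation), with 6 of 31 lower over all genes and 11 adjusted over the list alone, and Alox12b fell by 0.71 (SE 0.14). The tight junction median was -0.13 (adjusted p = 0.0447, and 0.601 with an estimated correlation), with 4 of 35 lower over all genes and 4 adjusted over the list alone. Cldn1 fell by 0.45 (SE 0.14, other probe -0.15) and Cldn15 by 0.41 (SE 0.08). The suprabasal median was -0.15 (adjusted p = 0.0447, and adjusted p = 0.745 with an estimated correlation), with 3 of 27 lower over all genes and 3 adjusted over the list alone. Basal keratinocyte genes had a median of -0.15 (adjusted p = 0.0346, and adjusted p = 0.601 with an estimated correlation), with 3 of 18 lower over all genes and 4 adjusted over the list alone. Cholesterol synthesis had a median of -0.18 (adjusted p = 0.0432, and adjusted p = 0.745 with an estimated correlation), with 5 of 25 lower over all genes and 5 adjusted over the list alone. In the epidermal lipid, tight junction and basal lists 1 gene each rose, over all genes and adjusted over the list alone. The cornified envelope median was -0.08 (adjusted p = 0.353) without a call, with Scel, at -0.90 (SE 0.18), and Ppl, at -0.80 (SE 0.18), among the 4 that fell. Flg (-0.03, SE 0.32), Lor (0.18, SE 0.35) and Tgm1 (-0.09, SE 0.17) did not pass.

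Most of these barrier calls depended on single arrays. Without after-SDS array 4 the suprabasal median turned to 0.02, and tight junction (-0.06), basal (-0.06) and cholesterol genes (-0.03) lost their calls. Without before-SDS array 3 calls were lost for suprabasal (-0.16), tight junction (-0.13), basal (-0.17) and cholesterol genes (-0.17). Without before-SDS array 2 they were lost for suprabasal (-0.08) and cholesterol genes (-0.12), without after-SDS array 2 for suprabasal (-0.15) and cholesterol genes (-0.09), and without after-SDS array 1 for tight junction genes (-0.12). Without before-SDS array 1 the medians were -0.30 for ceramide, -0.30 for suprabasal and -0.23 for basal genes, and the cornified list passed at -0.27. Without after-SDS array 3 the medians were -0.26 for suprabasal and -0.25 for basal genes.

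Lists of the dermis and of other cell types had medians of either sign in GC-fed skin. Endothelial markers had a median of -0.27 (adjusted p = 0.0094, and adjusted p = 0.551 with an estimated correlation), with 5 of 17 lower and 1 higher over all genes and 7 and 1 adjusted over the list alone, and Cdh5, a junction protein of vessels, fell by 0.29 (SE 0.07). Collagen and extracellular matrix genes had a median of -0.23 (adjusted p = 0.022, and adjusted p = 0.697 with an estimated correlation), with 7 of 34 lower over all genes and 8 adjusted over the list alone, and Eln, elastin, fell by 0.62 (SE 0.10). Skeletal muscle markers had a median of -0.34 (adjusted p = 0.0204, and adjusted p = 0.716 with an estimated correlation), with 3 of 30 lower over all genes and 3 adjusted over the list alone, and Mb, myoglobin, fell by 0.83 (SE 0.16). Sebaceous markers had a median of -0.21 (adjusted p = 0.0232, and adjusted p = 0.551 with an estimated correlation), with 3 of 16 lower over all genes and 6 adjusted over the list alone. Dendritic and Langerhans cell markers had a median of -0.13 (adjusted p = 0.0303, and adjusted p = 0.485 with an estimated correlation), with 4 of 17 lower over all genes and 6 adjusted over the list alone, and Cd207, the Langerhans cell protein langerin, fell by 1.02 (SE 0.13). Clock genes had a median of -0.31 (adjusted p = 0.0094, and adjusted p = 0.485 with an estimated correlation), with 5 of 18 lower over all genes, and 9 lower and 1 higher adjusted over the list alone. B and plasma cell markers were higher at 0.14 (adjusted p = 0.0235, and adjusted p = 0.485 with an estimated correlation), 1 of 9 over all genes and 4 adjusted over the list alone. Erythrocyte markers were higher at 0.43 (adjusted p = 0.0232, and adjusted p = 0.485 with an estimated correlation), 2 of 6 over all genes and 2 adjusted over the list alone.

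Of these calls, those for collagen were lost without before-SDS array 1 (-0.15) or 3 (-0.20) or after-SDS array 3 (-0.11), and its median was -0.39 without after-SDS array 4. Muscle lost its call without before-SDS array 3 (-0.22) or after-SDS array 1 (-0.25) or 3 (-0.15), and endothelial markers theirs without after-SDS array 3 (-0.14). Dendritic markers lost theirs without before-SDS array 1 (-0.15) or after-SDS array 2 (-0.17) or 3 (-0.08), and were at -0.30 without after-SDS array 4. Sebaceous markers lost theirs without before-SDS array 2 (-0.15) or after-SDS array 4 (-0.23), B and plasma cell markers without before-SDS array 3 (0.15) or after-SDS array 4 (0.14), and erythrocyte markers without before-SDS array 3 (0.41) or after-SDS array 4 (0.16). B and plasma cell markers were at 0.35 without after-SDS array 3. Lists without a call were cytokine (0.14, adjusted p = 0.107), neutrophil (0.44, 0.135), adipocyte (-0.05, 0.491), mast cell (-0.11, 0.216), interferon (0.05, 0.491) and macrophage (0.02, 0.583).

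The largest changes in GC-fed skin were rises of Slc4a7 by 4.28 (SE 1.15) and of hair follicle proteins, with Krtap4-13 at 2.42 (SE 0.59), Krtap14 at 2.14 (SE 0.58), Krt33a at 2.06 (SE 0.54) and Krtap3-1 at 1.97 (SE 0.49). Sct rose by 2.22 (SE 0.42). Scd3 fell by 1.70 (SE 0.18), Cthrc1 fell by 1.44 (SE 0.29), Csrp3, a protein of striated muscle, fell by 1.34 (SE 0.22), Myom3 fell by 1.21 (SE 0.17), Clca3a1 fell by 1.20 (SE 0.17) and Pink1, a mitochondrial kinase, fell by 1.13 (SE 0.24). In all limma called 2329 genes, 1040 up and 1289 down, with 5160 at an unadjusted p under 0.05 and a lowest adjusted p of 2.4e-05. Median centring moved this split to 378 up and 823 down of 1201, and with no normalization between arrays 0 genes passed. The count was 558 without before-SDS array 2, 584 without before-SDS array 3, 981 without after-SDS array 3 and 2745 at most. Of the 82 named genes that passed, 52 lost the call without before-SDS array 2 and 51 without before-SDS array 3, and 24 passed without each array in turn, among them Krt35, Krt85, Aurka, Plk1, Cers5, Alox12b, Scd3, Eln, Mb and Cd207. The camera test called 18 lists, from 9 (without before-SDS array 3) to 18 without 1 array, and 0 with an estimated correlation. By fry 7 lists passed (lowest adjusted p 0.0105).

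**Figure D3:**
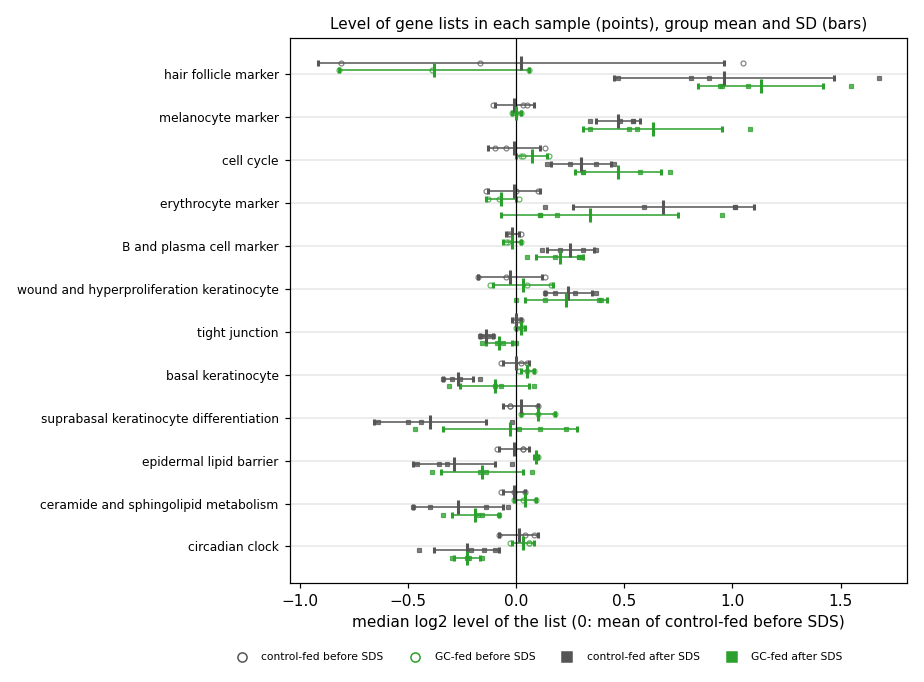
Median log2 level of 12 gene lists (y axis) in each sample (x axis, 0 being the mean of control-fed samples before SDS), in grey for control-fed and green for GC-fed skin, with open circles before SDS (3 samples per diet) and filled squares after SDS (4 samples per diet); vertical bars are group means and horizontal bars the SD. Hair follicle and cell cycle lists had higher means after SDS in both diets, and ceramide and clock lists lower. Samples overlapped in control-fed skin, with hair follicle at 1.05 and ceramide at -0.07 on before-SDS array 2 and at 0.47 to 1.68 and -0.48 to -0.04 after SDS. The tests cannot part SDS from slide, and called 0 lists with an estimated correlation. By fry, hair follicle (adjusted p 0.0757) and cell cycle genes (0.104) did not pass in control-fed skin.

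Many of the same genes passed in both diets. Of the called genes 612 rose and 872 fell in both, where 69.2 and 109.2 would be expected if the calls were independent, and 0 went in opposite directions. The fold changes correlated across genes at r = 0.815, but both effects came from the same arrays, and genes are not independent replicates. Whether SDS acted differently in the diets is the same question as the third comparison, in which 0 genes passed (207 at an unadjusted p under 0.05). As labelled, Krt35, Aurka, Cers5, Scd3 and Cldn1 passed in the same direction in both diets. Il1b, Krt16, Gpd1 and Adipoq passed in control-fed skin alone, while the test of the difference passed for none of them.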

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

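The tests of exchanged diets and of muscle and fat content on after-SDS array 4, and both tests of a general interferon response, were chosen only after the result was seen; the others were written down before.

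Of 280 groups of 4 samples, 20 had 1 sample far from the other 3, where chance gives about 1 in 20. Among diet ratios after SDS these were array 4 for Tgm1 (-0.54), Mki67 (-0.39), Dst (-0.24), Igtp (0.04) and the collagen list (0.51), array 3 for the endothelial list (-0.48) and Tpsb2 (-1.01), and array 1 for Acaa2 (0.43). Among levels of control-fed skin after SDS the stray samples were at 9.79 for Il1b, 10.86 for Krt2, 11.54 for H1f10, 9.5 for Alox12b, 13.08 for Plin1 and 10.19 for Clec4d. Among levels of GC-fed skin after SDS they were at 13.21 for Krtap4-13, 13.13 for Krtap19-9b, 11.43 for Krtap26-1, 9.93 for Casp14, 10.32 for Lox and 11.06 for Alas2.

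The diet effect differed between skin after and before SDS for 13 lists by camera at the preset correlation, none of which passed with an estimated correlation (adjusted p = 0.916 at the lowest). The median differences were 0.25 for cornified envelope, 0.22 for suprabasal differentiation, 0.11 for cell cycle and 0.39 for hair follicle genes. They were -0.13 for cytokine, -0.11 for interferon, -0.03 for heat shock, -0.49 for muscle, -0.28 for adipocyte, -0.02 for sebaceous, -0.14 for endothelial, -0.07 for T and NK cell and -0.25 for mast cell genes.

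On after-SDS array 4, 0.938 of the 224 genes with a ratio beyond 1 opposed the mean of arrays 1 to 3, whereas 0.88, 0.914 and 0.804 of such genes on arrays 1, 2 and 3 went with the mean of the others. A different content of muscle and fat in the skin pieces was argued against, as the muscle median on array 4 (-0.32) had the sign of the other 3 arrays. An exchange of the diets between the channels of this array may account for most of the opposed genes. Across genes, its GC-fed channel correlated at 0.62, 0.47 and 0.5 with the control-fed channels of after-SDS arrays 1 to 3. With their GC-fed channels it gave 0.01, -0.39 and -0.19. Its control-fed channel gave 0.05, 0.02 and 0.23 with control-fed and 0.2, 0.35 and 0.14 with GC-fed channels. The fat (-0.24), muscle (-0.32) and mast cell (-0.08) lists kept their direction as labelled, so the exchange stayed open. It would also misplace both channels in the SDS comparisons. A weaker or stronger response to SDS in the paired samples, the biological alternative, stayed open. Across genes, array 4's ratio correlated with the SDS effect from the other arrays at r = 0.17. After-SDS arrays 1 to 3 gave -0.42, -0.32 and -0.06. The before-SDS arrays, without SDS, gave 0.28, -0.41 and -0.06, so this measure cannot decide. Of the 8 ways to exchange signs among the 4 after-SDS arrays, 8 gave at least the real count of 0 genes, as any exchange must, and the highest (1837) was the exchange of array 4, which points to a structure of the samples; 8 are too few for a share under 0.05.

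The SDS calls (2588 and 2329 genes) were set by arrays of 1 slide against arrays of another. Of 34 splits into 3 and 4 arrays, only the real one, also the slide split, gave as many genes. The highest other gave 2 in control-fed and 1 in GC-fed skin, so chance is unlikely. A slide effect on single probes stayed open: second probes of called genes had the same sign in 0.71 of cases in control-fed and 0.711 in GC-fed skin, above the 0.594 and 0.588 of genes not called. Among genes beyond 2-fold the shares were higher, 0.806 (25 of 31) and 0.923 (24 of 26), but these are the top genes alone. A slide effect on all probes of a gene cannot be told apart from SDS, as 0 slides held arrays of both groups. The effect of SDS itself is the biological explanation that the design names, and it stayed open as well.

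As labelled, Ifi27l2a was lower with GC on all 7 arrays, at -0.84, -1.07 and -1.61 before and -2.03, -0.85, -5.08 and -6.1 after SDS. A fault of a single probe was excluded, as its other probe was lower on 7 arrays (-0.69 to -4.43). A lower interferon response in general was excluded on array 4, where the other 36 interferon genes had a median of 0.16 with 27 of them higher. On the other 6 arrays it could be part of the difference, as the highest median there was 0.03 and the test did not decide. A difference in genotype between the mice was not tested.

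For the diet effect before SDS, 4 of 4 sign exchanges gave at least the real count of 0 genes (highest other 0), too few for a share under 0.05. For the difference of the diet effect, 34 of 34 splits gave at least the real count of 0 (highest other 0). Any exchange or split reaches a count of 0, so neither test decides anything about chance.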

How the results depend on the processing

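Alternatives with the sign of an array turned, and those without after-SDS arrays 1 and 4 together, were chosen only after the result was seen. Where a cause is not given below, the cause was not tested. No named gene that passed, as reported or under the alternative, changed direction under any alternative run, and the direction of a list is that of its test. Slide as a block was not run, since 0 slides held more than 1 group, and depth is limited by spots near background, 48.5% to 54.5% of green spots being well above it.

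Diet counts of genes stayed at 0 under all alternatives fixed in advance, except without after-SDS array 4. With the sign of after-SDS array 4 turned, limma called 1837 genes for diet after SDS and 123 for the difference, and with before-SDS array 1 turned as well, 3242 and 371. SDS counts in control-fed and GC-fed skin were 1167 and 1201 with median centring, 1277 and 1142 with the mean of a gene's probes, 1588 and 1018 in the authors' table, which holds fewer genes, and 0 and 0 with no normalization between arrays. Agilent's processed signals gave 1236 in GC-fed skin. SDS counts were 1695 and 3557 with before-SDS array 1 turned, 4347 in control-fed with array 4 turned and 4676 in GC-fed with both turned.

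Leaving out 1 array gave 0 to 926 genes for diet after SDS, 0 to 56 for the difference, 154 to 3688 for SDS in control-fed and 558 to 2745 in GC-fed skin. Lists called ranged from 9 to 17 for diet before, 12 to 22 for diet after, 8 to 24 for the difference, 10 to 20 for SDS in control-fed and 9 to 18 in GC-fed skin. The cornified median ranged from -0.06 to 0.57 before, 0.10 to 0.60 after and -0.37 to 0.62 for the difference, and the tight junction median from -0.01 to 0.07, 0.02 to 0.19 and -0.10 to 0.12.

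Lists called with an estimated correlation were 0 before, 0 after, 0 for the difference, and 0 in control-fed and 0 in GC-fed skin. By fry they were 0, 0 and 0 for the diet comparisons and 7 and 7 for SDS. The cornified list's adjusted p was 0.887, 0.63 and 0.941 with an estimated correlation, and 0.997, 0.675 and 0.974 by fry, before, after and for the difference. Lists called were 25 after SDS with array 4 turned and 23 with both turned, 24 for the difference with array 4 turned, and 9 before SDS without the dye term. In GC-fed skin SDS lists were 9 with all 14 channels above background, 10 in the authors' table, 11 with replicate number as a block and 10 with array 4 turned.

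The cornified list before SDS lost its call without the dye term (0.03), with array weights (0.04), with only the arrays of the comparison (0.03) and with array 4 turned (0.04), and its difference did without the filter on dim probes (0.23). The tight junction list passed before SDS with no background correction (0.03) and with before-SDS array 1 turned (0.06). It passed after SDS with all 14 channels above background (0.12), with array 4 turned (0.15) and with both turned (0.16), and for the difference with array 4 turned (0.12).

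Directions turned as follows. With before-SDS array 1 turned, medians before SDS were -0.12 for cell cycle, -0.07 for heat shock, -0.13 for collagen and 0.36 for muscle, and differences were -0.39 for cornified, -0.09 for suprabasal, 0.02 for cytokine and 0.04 for heat shock. With both turned, medians before SDS were -0.31 for cell cycle, 0.11 for interferon, -0.05 for heat shock, -0.01 for collagen and 0.63 for muscle, and cholesterol synthesis in GC-fed skin under SDS was 0.08. With array weights the hair follicle difference was -0.07. With the replicate block the sebaceous difference was 0.05 and the suprabasal median in GC-fed skin under SDS 0.02; replicate numbers did not pair the arrays (r of -0.09, -0.04 and 0.19). Leaving out 1 array turned medians before SDS of cornified (-0.06 to 0.57), cell cycle (-0.06 to 0.11), heat shock (-0.06 to 0.10), collagen (-0.06 to 0.15), muscle (-0.33 to 0.17) and hair follicle genes (-1.50 to 0.23). It turned differences of cornified (-0.37 to 0.62), suprabasal (-0.14 to 0.50), cytokine (-0.38 to 0.02), heat shock (-0.20 to 0.04), hair follicle (-0.21 to 1.42), cell cycle (-0.07 to 0.25) and interferon genes (-0.23 to 0.06), and the suprabasal median in GC-fed skin under SDS (-0.30 to 0.02). No other called list's test turned. Medians changed sign while the test lost its call for the sebaceous difference (0.03 with Agilent's processed signals, 0.01 without before-SDS array 2, 0.09 with both turned), and for the endothelial (0.01 without after-SDS array 3), heat shock (0.03 with both turned) and hair follicle differences (-0.11 with the replicate block).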

Other observations

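The counts over all 7 arrays and the spread of Slc4a7 were chosen only after the result was seen, and the list tests were not. After SDS in control-fed skin, interferon response (median 0.17, adjusted p = 0.0533), macrophage (0.21, 0.0575), muscle (0.24, 0.0654) and heat shock genes (0.17, 0.199) had positive medians without passing in camera, and so had NRF2 genes (0.19, 0.402). Collagen (-0.13, 0.0575), endothelial (-0.12, 0.29), dendritic (-0.07, 0.282), sebaceous (-0.07, 0.57) and PPAR target genes (-0.04, 0.659) had negative medians without passing. T and NK cell markers were at 0.03 (0.94), and nerve and Schwann cell markers at -0.03 with an upward test (0.95). In GC-fed skin the NRF2 median was 0.03 with a mean of -0.04 (0.779), heat shock genes were at -0.01 (0.779), PPAR targets at -0.14 (0.182), T and NK cell markers at -0.06 (0.244) and nerve markers at -0.05 (0.74).

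In GC-fed skin 93 genes were lower and 53 higher on all 7 arrays as labelled, and 430 were lower and 319 higher with the sign of after-SDS array 4 turned. If the arrays were independent, 134 would be expected in each direction, but after-SDS array 4 ran against the other after-SDS arrays (r = -0.3 to -0.62). As labelled, the only 1 of these genes with every ratio beyond 0.5 was Ifi27l2a. The spread of Slc4a7 after SDS was wide in both diets, with an SD of 1.97 in control-fed and 2.12 in GC-fed skin.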
